A study of Mus musculus with 27 samples.

How the data were processed

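The study measured RNA in CT26 tumors, a transplantable mouse colon carcinoma line grown under the skin of BALB/c mice, after knockout of Mettl3, of Mettl14 or with a control guide RNA. Of the 27 samples in the series, the 15 RNA-seq samples were analysed, 5 in each group. The 12 methylated RNA immunoprecipitation samples (6 with the m6A antibody and 6 inputs) were not analysed here. Groups and replicate numbers came from the sample titles. The genotype field of the samples titled Mettl14 names Mettl4, and the title was followed because the count table and the series design also name Mettl14. The labels give tumors of separate mice in general terms but do not tie each sample to an animal, so p-values measure the spread between these samples.

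Per the labels' protocols, RNA from tumors was fragmented and sequenced as single reads of 75 nucleotides on an Illumina HiSeq4000. Those protocols mention both ribosomal RNA depletion and poly(A) selection, and the molecule label of the RNA-seq samples is polyadenylated RNA. Per the submitters' processing notes, the tools were cutadapt 1.18, HISAT2 2.1.0, HTSeq 0.11.2 and DESeq2, with the mm10 build. The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited raw read counts per Ensembl gene, 1 table per knockout, each with the same 5 control columns, which held identical values in both tables and were used once. The count tables end in lines for reads assigned to no gene, here called reads outside genes, and for ambiguous, multiply aligned and unaligned reads. These lines held 56.8% to 86.2% of all reads of a library and were left out of library sizes and tests. Since the counting settings are not fully stated, reads outside genes may include reads in introns or antisense to genes. The authors also deposited a table of log2 fold changes with standard errors, p-values and adjusted p-values for each knockout, with column names that DESeq2 writes, per the file headers. Settings behind those tables are not given in the sources used here, and their values are printed only where the authors' deposited table is named.

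Counts were read for 54752 genes, of which 54723 IDs matched a symbol. Gene positions and exon lengths were taken from the GENCODE M21 annotation of mm10. Reads from genes with near-identical copies (hemoglobin, guanylate-binding protein, immunoglobulin and major histocompatibility genes), and from overlapping or antisense genes, cannot be assigned with certainty, since the strand setting is not stated. All 30 pairs of replicates within groups differed by more than sampling noise (smallest chi-square per gene 15.8), so every library was counted as 1 sample.

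Each knockout was compared with control by the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, fitted to the 10 libraries of that comparison. Genes were filtered with filterByExpr at a minimum count of 10, scaled by trimmed mean of M-values (TMM), fitted with robust dispersion and adjusted by Benjamini-Hochberg at a threshold of 0.05. Standard errors of log2 fold changes were computed from the F statistic. The difference between the knockouts was tested in a fit of all 15 libraries. Levels are given as CPM, the reads of a gene scaled to a common library total, on a TMM scale over the 15 libraries, as mean ± SD with n = 5 throughout.

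Before the data were examined, 31 gene lists were fixed for the tumor, its immune cells, its neighbouring tissues and cell processes (450 of 451 genes found). They were m6A writers, erasers and readers; interferon-gamma response; type I interferon response; MHC class I and class II antigen presentation; chemokines and cytokines; T cell, regulatory T cell, B cell and plasma cell, macrophage, neutrophil, dendritic cell and endothelial markers. They also held cytotoxic lymphocyte, immune checkpoint and exhaustion, fibroblast and matrix, skeletal muscle, keratinocyte, adipocyte, erythroid, epithelial, cell cycle, hypoxia and glycolysis, TGF-beta and mesenchymal, p53 target, unfolded protein response and Wnt target genes. The last 4 were nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal protein, and immediate early and heat shock genes. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 31 lists. Alternatives were camera with an estimated correlation and fry. The median of a list was also placed among 10000 random lists matched on abundance in 50 bins.

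The genes named were set by a rule, also fixed before the data were examined. It took 8 genes in both knockout comparisons, among them Mettl3, Mettl14, Irf1, Ifng, Cxcl9, Cxcl10 and Ccl5. Some genes that the rule took are not reported here. It took the 8 largest rises and 8 largest falls per knockout with adjusted p under 0.05, a mean of at least 1 CPM and every knockout library on the same side of the control mean, leaving out gene models and pseudogenes. Where none passed, it took the 3 with the smallest unadjusted p in each direction. It took 2 to 4 members with the smallest adjusted p of each list described, and the 8 largest mean rises and falls of genes changed in both knockouts, of which there were none. Which lists were described with examples was chosen after the list results had been seen.

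Several measures were added after the data were seen, once the camera calls were known to be lost with an estimated correlation. The first was an exact permutation test of list scores, the mean log2(CPM + 2) of a list's genes per library, with a smallest possible two-sided p of 0.00794 for 5 against 5. Others were the same exact test for the first 8 named genes (adjusted over 16 tests), the random lists matched on abundance, and comparison with genes of like abundance. Background was measured as reads on 1459 protein-coding olfactory and vomeronasal receptor genes, which tumors are not known to use, and as reads outside genes. Unlike other levels, receptor gene CPM were taken per total gene counts, without TMM scaling. The satellite-like gene models, also chosen after the data were seen, were Gm10800, Gm10801, Gm10717, Gm10722 and Gm21738. Background entered as a covariate (log2 ratio of reads outside genes to reads in genes) or was subtracted per kb of exon. Fits of all 15 libraries with further tools, fits without the libraries richest in reads outside genes, and counts thinned to the smallest total were also added. So were the plain fit of all samples for genes changed in both knockouts and library totals for the count of genes differing between the knockouts.

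Alternatives chosen beforehand were relative log expression (RLE) scaling, library totals, other filters, DESeq2 1.42.0, voom with and without sample weights, 1 fit of all samples, the replicate number as a block, a T cell score covariate, a fold change minimum, split controls and each library left out in turn. Because the controls were shared, unchanged groups were simulated against them in 20 draws. The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For Mettl3 KO against control, run on 20713 genes, edgeR recovered 31% and 86% of these with 5 false calls, and DESeq2 recovered 56% and 95% with 56 false calls. For Mettl14 KO, on 20248 genes, edgeR recovered 42% and 88% with 4 false calls, and DESeq2 60% and 95% with 49. Between the knockouts, on 23798 genes, edgeR recovered 52% and 90% with 9 false calls, and DESeq2 66% and 97% with 51. The simulated genes varied independently, without structure shared across a library. These recovery and false call figures may therefore not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.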

Results

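Mettl3 and Mettl14 form the enzyme complex that places N6-methyladenosine (m6A) on messenger RNA. The series asked which genes differ between tumors that lack either protein and control tumors under anti-PD-1 therapy, an antibody treatment that releases T cells from a checkpoint. CT26 cells carrying a guide RNA against Mettl3, against Mettl14 or a control guide were grown as tumors. Antibodies were given at 200 µg (10 mg/kg) from day 11 to day 23, per the labels' protocols. These protocols also list anti-CTLA-4 and IgG, and only the series design ties these samples to anti-PD-1. Tumor RNA was sequenced from 5 samples per group.

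Control replicates 1 to 5 had 5.52, 12.5, 13.7, 18.1 and 20.98 M reads (M for mega) counted on genes. The Mettl3 KO replicates had 5.21, 9.33, 6.25, 4.35 and 7.70 M, and the Mettl14 KO replicates 17.0, 6.45, 7.55, 12.7 and 9.24 M. The group means were 14.2 ± 5.91, 6.57 ± 1.99 and 10.6 ± 4.30 M (SD, n = 5). The difference between Mettl3 KO and control had p = 0.0317 by a two-sided exact permutation test, and p = 0.245 after Benjamini-Hochberg adjustment over the 24 library comparisons.

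Reads assigned to no gene, called reads outside genes, may include intronic or antisense reads. They made up 54.8% ± 13.9 of uniquely aligned reads in control, 68.3% ± 7.16 in Mettl3 KO and 58.5% ± 5.25 in Mettl14 KO tumors. Control replicate 1 stood at 78.6%, while the other 4 controls lay between 44.3% and 53.8%. Olfactory and vomeronasal receptor genes, which sense odors and pheromones in the nose, took 1430 ± 2200 CPM in control, 2832 ± 1420 in Mettl3 KO and 1162 ± 551 in Mettl14 KO libraries. Across the 15 libraries their share tracked the share of reads outside genes (Pearson r = 0.952 and Spearman rho = 0.993, permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without the 2 libraries farthest from the median, r was 0.937. Mitochondrially encoded RNA took 5.53% ± 2.28 of gene counts in control, 1.95% ± 0.498 in Mettl3 KO (exact permutation p = 0.00794, adjusted p = 0.190) and 4.12% ± 1.01 in Mettl14 KO libraries. A set of 5 satellite-like gene models took 4.90% ± 9.28 of gene counts in control, 25.5% ± 16.7 in Mettl3 KO (exact permutation p = 0.0556, adjusted p = 0.245) and 3.19% ± 2.90 in Mettl14 KO libraries. As these models count in the total, they lower the receptor and mitochondrial shares of libraries rich in them. None of the 24 library comparisons with control passed adjustment. The mitochondrial share, at the smallest possible exact permutation p of 0.00794, still had an adjusted p of 0.190. The lack of a passing result therefore does not show that the libraries were alike.

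**Figure D1:**
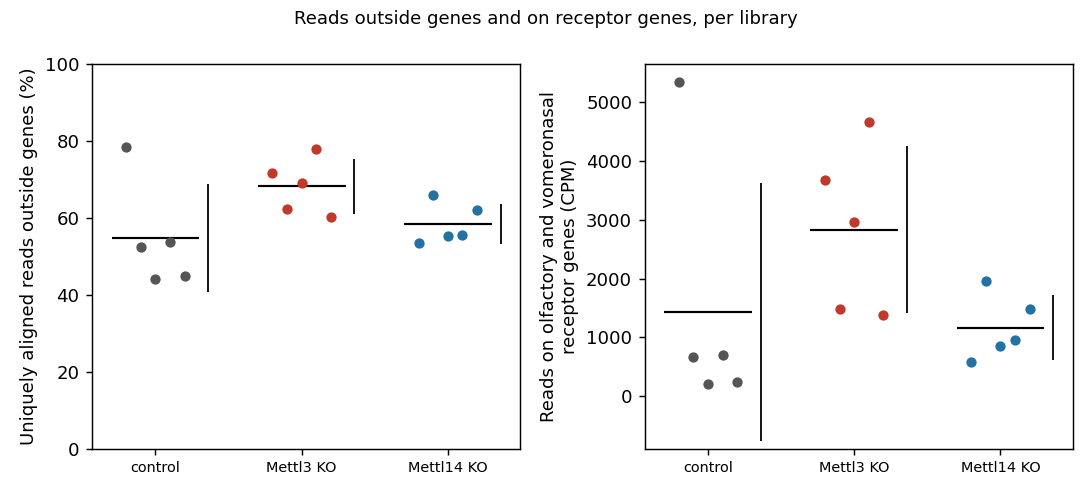
Share of uniquely aligned reads assigned to no gene, called reads outside genes (left, percent), and CPM on olfactory and vomeronasal receptor genes (right) in each of the 15 libraries, with points for libraries, horizontal lines for group means and vertical lines for SD. Control replicate 1, at 78.6% and 5343 CPM, lies apart from the other 4 controls, at 44.3% to 53.8%.

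The targeted genes were examined first. Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, mm10) stood at 13.8 ± 1.45 CPM in Mettl3 KO and 19.5 ± 3.59 CPM in control tumors (n = 5 each), with every knockout library under the control mean. Control replicate 1, at 13.5 CPM, lay inside the range of the knockout libraries (12.5 to 16.3 CPM). Its log2 fold change of -0.56 (SE 0.15) had an adjusted p of 0.0545 by edgeR, and was -0.23 against genes of like abundance. The exact permutation test of its level, added after the data were seen, gave p = 0.0317 and an adjusted p of 0.0462. Mettl14 (ENSMUSG00000028114, chromosome 3, 123368297 to 123386108) stood at 61.6 ± 12.4 CPM in Mettl14 KO and 69.5 ± 11.7 CPM in control tumors, a log2 fold change of -0.21 (SE 0.17, edgeR adjusted p = 0.735). A guide RNA edits DNA and can leave the transcript in place, and tumors hold host cells, so these RNA levels are a weak check of the labels.

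**Figure D2:**
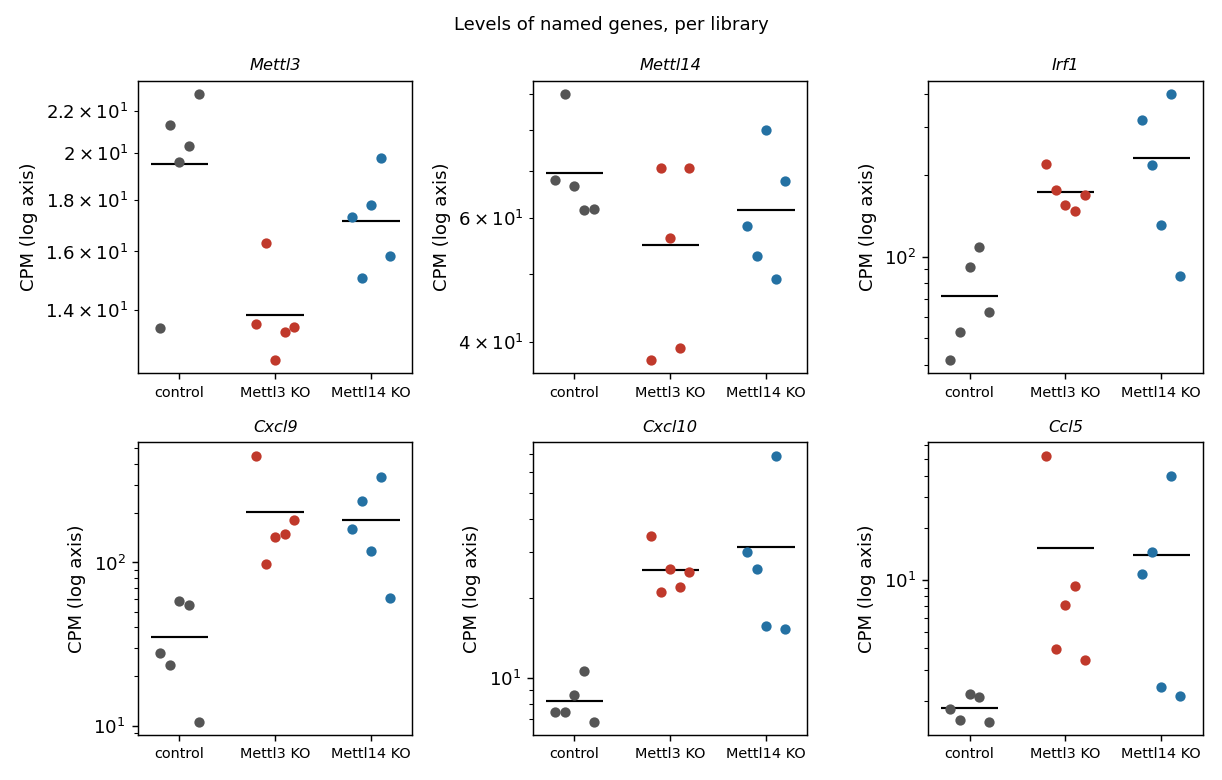
Levels in CPM (log axis) of Mettl3, Mettl14, Irf1, Cxcl9, Cxcl10 and Ccl5 in each of the 15 libraries, with points for libraries and lines for group means. All Mettl3 KO libraries lie above all control libraries for Irf1, Cxcl9, Cxcl10 and Ccl5, and the Mettl14 KO libraries spread widely, from 85.2 to 397.5 CPM for Irf1.

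In Mettl3 KO tumors, genes that respond to interferon-gamma, the T cell cytokine that arms macrophages and tumor cells, were higher than in control tumors. Of 22 such genes, 18 rose over all genes tested and 20 when adjusted over the list alone, with a median log2 fold change of 1.64. Irf1, a transcription factor induced by interferon, rose from 71.3 ± 27.9 to 173.6 ± 28.6 CPM (log2 fold change 1.23, SE 0.25, edgeR adjusted p = 0.0463). The guanylate-binding proteins, GTPases that attack intracellular pathogens, rose in the same tumors, with log2 fold changes of 1.68 for Gbp7 (SE 0.20), 1.93 for Gbp3 (SE 0.24), 1.91 for Gbp5 (SE 0.25) and 2.29 for Gbp4 (SE 0.32).

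The 4 interferon-gamma response genes that did not pass over all genes were Irf8, Nlrc5, Socs1 and Wars, with log2 fold changes of 0.90, 0.74, 0.12 and 0.33. They were named after their values were seen. The list passed camera with the preset correlation (adjusted p = 1.634e-16) but not with an estimated one (adjusted p = 0.460 with an estimated correlation). The list score was 6.64 ± 0.25 in Mettl3 KO and 5.09 ± 0.41 in control tumors, higher in 5 of 5 knockout libraries than in every control (exact permutation p = 0.00794, adjusted p = 0.0308). The type I interferon list, which marks antiviral defence, had 4 of 25 genes that rose and 13 when adjusted over the list alone, with a median log2 fold change of 0.62. The 4 were Zbp1 (1.74, SE 0.24), Oasl2 (0.99, SE 0.16), Stat2 (0.98, SE 0.16) and Rtp4 (1.05, SE 0.19). Camera gave that list an adjusted p of 9.309e-08, and an adjusted p = 0.460 with an estimated correlation.

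Antigen presentation and chemokine genes were higher as well. Of 8 measured MHC class II genes, which show peptides to helper T cells, 3 rose and 8 did when adjusted over the list alone, with a median log2 fold change of 2.58. They were Ciita, the master activator of the class (64.3 ± 25.5 against 9.18 ± 4.74 CPM, log2 fold change 2.77, SE 0.42), H2-DMb1 (2.65, SE 0.48) and H2-DMa (1.84, SE 0.31). Of 17 MHC class I genes none passed over all genes and 10 rose when adjusted over the list alone (median 0.54), led by Tap1 (1.06, SE 0.24) and Psmb9 (1.14, SE 0.26), both with an edgeR adjusted p of 0.0524. Of 14 chemokines and cytokines, Cxcl9 and Cxcl10, which draw T cells, rose over all genes, and 10 rose and 1 fell when adjusted over the list alone (median 1.54). Cxcl9 rose from 35.0 ± 20.6 to 204.8 ± 141.1 CPM (2.52, SE 0.52), with 451.3 CPM in replicate 1, and Cxcl10 from 8.19 ± 1.49 to 25.7 ± 5.28 CPM (1.59, SE 0.19). Ccl5 stood at 15.2 ± 20.8 against 1.82 ± 0.304 CPM (edgeR adjusted p = 0.0524), with 52.2 CPM in replicate 1. Ifng itself stood at 2.91 ± 2.01 against 0.883 ± 0.690 CPM and was below the count filter (exact permutation p = 0.0556, adjusted p = 0.0741). Camera gave the MHC class II, MHC class I and chemokine lists adjusted p of 5.67e-07, 4.833e-05 and 0.00125, and each had an adjusted p = 0.460 with an estimated correlation.

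Lymphocyte genes lay higher in the same tumors. Of 15 T cell markers 1 rose over all genes, and 13 rose when adjusted over the list alone (median 1.43). The kinase Lck had a log2 fold change of 1.23 (SE 0.29, adjusted p = 0.0524). Of 15 cytotoxic lymphocyte genes, the activating receptor Klrk1 rose (1.92, SE 0.33), and 10 rose when adjusted over the list alone (median 1.17). Klrc1 had 1.63 (SE 0.38, adjusted p = 0.0524). None of 11 checkpoint and exhaustion genes passed over all genes and 7 rose when adjusted over the list alone (median 0.72), with 1.90 for Btla (SE 0.43) and 1.79 for Pdcd1 (SE 0.42), which encodes PD-1. None of 11 dendritic cell markers passed over all genes, and 7 rose and 1 fell when adjusted over the list alone (median 1.32), with 0.88 for Wdfy4 (SE 0.21) and 2.02 for Xcr1 (SE 0.62), which stood at 5.52 CPM in control replicate 1 and at most 1.32 in the other controls. None of 11 B cell and plasma cell genes passed over all genes and 4 rose when adjusted over the list alone (median 1.90). Igkc, an antibody light chain, had 84.3 ± 177.4 against 1.08 ± 0.450 CPM, with 401.7 CPM in replicate 1 and at most 8.82 in the others. The heavy chain Ighm had 55.4 ± 80.2 against 6.52 ± 4.14 CPM. These 5 lists passed camera (adjusted p from 3.597e-06 for T cells to 0.00276 for checkpoint genes). With an estimated correlation, adjusted p = 0.460 for the first 4 and 0.474 for the B cell list.

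Genes of red blood cells were lower. Of 6 erythroid genes, 3 fell and 5 did when adjusted over the list alone (median log2 fold change -2.01), namely Hbb-bt (-2.74, SE 0.59), Hbb-bs (-2.62, SE 0.47) and Hba-a1 (-2.16, SE 0.44). Hbb-bs, a beta-globin, stood at 15.3 ± 7.60 against 89.8 ± 60.9 CPM. Reads of these hemoglobin genes can be shared between near-identical copies. The list passed camera (adjusted p = 0.0372) and had an adjusted p = 0.474 with an estimated correlation. Its score was lower in 5 of 5 knockout libraries than in every control (exact permutation p = 0.00794, adjusted p = 0.0308). Among macrophage markers Cd163, a scavenger receptor for hemoglobin, fell from 38.7 ± 8.94 to 14.3 ± 3.07 CPM (-1.499, SE 0.20), and Fcgr1 had 0.88 (SE 0.22, adjusted p = 0.0524). When adjusted over the list alone, 1 of 16 macrophage markers rose and 3 fell, with a list median of -0.00419. Of 11 neutrophil markers Acod1, which makes itaconate and which macrophages also express, rose (2.51, SE 0.48), and Csf3r had 0.90 (SE 0.29, adjusted p = 0.0707). Of 9 epithelial genes Krt20, a keratin of intestinal epithelium, fell from 187.1 ± 23.7 to 57.7 ± 27.3 CPM (-1.76, SE 0.28), and Krt18 had -0.89 (SE 0.34, adjusted p = 0.105). The neutrophil and epithelial counts were the same when adjusted over the list alone, and neither they nor the macrophage list passed camera (adjusted p = 0.0742, 0.655 and 0.513).

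Ribosomal protein, mitochondrially encoded, p53 target and unfolded protein response genes also had medians below 0. Of 20 ribosomal protein genes Rpl5 fell (388.9 against 824.4 CPM, log2 fold change -1.14, SE 0.24), and 20 fell when adjusted over the list alone (median -0.93). Rpl23 had -0.93 (SE 0.21, adjusted p = 0.0524). None of 10 mitochondrially encoded genes passed over all genes and 6 fell when adjusted over the list alone (median -1.22), with -1.63 for mt-Nd4 (SE 0.38) and -1.06 for mt-Nd1 (SE 0.31). Of 11 p53 targets, Zmat3 (-1.06, SE 0.18) and Eda2r (-1.05, SE 0.18) fell, and 6 did when adjusted over the list alone (median -0.70). Of 12 unfolded protein response genes Dnajb9, a chaperone of the endoplasmic reticulum, fell (-1.30, SE 0.23), and 10 did when adjusted over the list alone (median -0.68). Hspa5 had -0.81 (SE 0.19, adjusted p = 0.0524). Camera gave these 4 lists adjusted p of 8.322e-07, 0.00507, 0.00483 and 0.000725, and with an estimated correlation an adjusted p = 0.474 for the mitochondrial list and 0.460 for the other 3.

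Abundant genes as a whole lay lower in this comparison. The median log2 fold change was 0.90 for 3232 genes at 1 to 2 CPM and -0.60 for the 444 most abundant genes. Against genes of like abundance, the medians were 2.19 for the interferon-gamma list, 3.08 for MHC class II, -1.75 for erythroid, -0.33 for ribosomal protein, -0.68 for mitochondrially encoded, -0.31 for p53 target and -0.15 for unfolded protein response genes. They were 0.95 for type I interferon, 1.07 for MHC class I, 1.10 for chemokine, 1.27 for T cell, 0.78 for cytotoxic lymphocyte, 1.07 for checkpoint, 1.197 for dendritic cell and 1.25 for B cell and plasma cell genes. For macrophage, neutrophil and epithelial genes they were 0.47, 0.21 and -0.16. The 19 m6A writers, erasers and readers, none of which passed over all genes and 14 of which fell when adjusted over the list alone, had a median of -0.49 but of 0.02 against genes of like abundance. Mettl3 and Ythdc1 (-0.62, SE 0.17, adjusted p = 0.0558) led that list. Cell cycle genes had a median of -0.36 (0.12 against like abundance), nuclear oxidative phosphorylation genes -0.57 (-0.06) and TGF-beta and mesenchymal genes -0.54 (-0.01), and keratinocyte genes 0.95 (0.15). Adjusted over the list alone, 6 of 17 oxidative phosphorylation genes and 1 of 14 TGF-beta and mesenchymal genes fell, and 0 of 23 cell cycle and 0 of 10 keratinocyte genes passed. Camera gave these 5 lists adjusted p of 0.000927, 0.00694, 0.000838, 0.0206 and 0.0102. With an estimated correlation, adjusted p = 0.460, 0.660, 0.474, 0.460 and 0.474. In all, camera passed 20 of the 31 lists in Mettl3 KO tumors, 11 higher and 9 lower, and 0 with an estimated correlation. The exact test of list scores, added after the data were seen, passed 10 lists in Mettl3 KO and 0 in Mettl14 KO tumors.

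**Figure D3:**
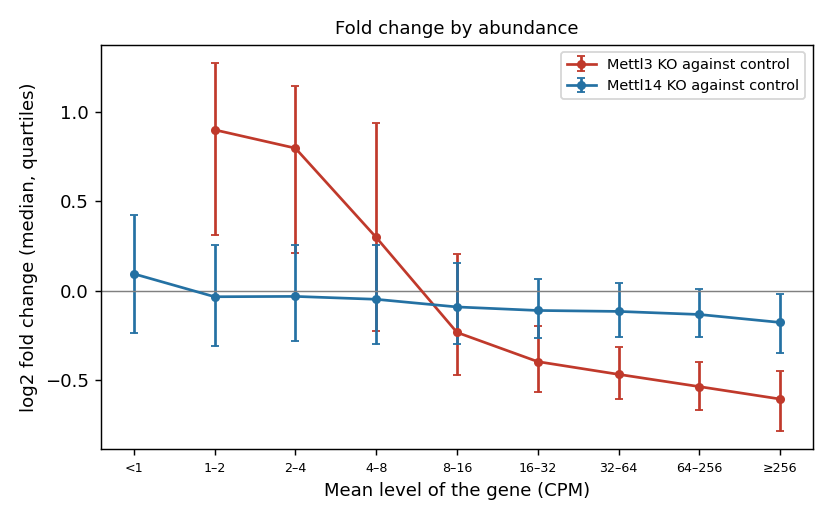
Median log2 fold change (points) with quartiles (bars) of genes grouped by mean level in CPM, for Mettl3 KO and Mettl14 KO against control. The bin under 1 CPM holds 16 genes for Mettl3 KO and is not drawn there; the Mettl3 KO medians run from 0.90 at 1 to 2 CPM to -0.60 in the most abundant genes, and the Mettl14 KO medians from 0.10 to -0.18.

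Over all genes, 266 of 21427 changed in Mettl3 KO tumors (edgeR quasi-likelihood test, Benjamini-Hochberg), 87 higher and 179 lower. The largest rises were in Calhm6 (log2 fold change 2.995, SE 0.63, 21.1 CPM in replicate 1), Ubd, a ubiquitin-like modifier (2.96, SE 0.41), Apol6 (2.86, SE 0.36), Ciita, H2-DMb1, Serpina3f (2.58, SE 0.41), Ido1, which breaks down tryptophan (2.55, SE 0.52), and Gbp10 (2.53, SE 0.32). Besides the 3 hemoglobin genes, the largest falls were in mt-Rnr1, a mitochondrial ribosomal RNA (-2.56, SE 0.42), Dhrs9 (-2.55, SE 0.28), Car6, a carbonic anhydrase (-2.38, SE 0.40), Lyve1, a receptor of lymphatic vessels (-2.12, SE 0.39), and Snora57, a small nucleolar RNA (-2.10, SE 0.36). In mm10, Ubd lies on chromosome 17 (37193892 to 37196095), Ciita on chromosome 16 (10480059 to 10528418), Dhrs9 on chromosome 2 (69380445 to 69404533) and Lyve1 on chromosome 7 (110850607 to 110863239). The balance of directions was not stable. More genes were higher than lower with RLE scaling (72 and 28), library totals (106 and 16), a mean of at least 1 CPM (68 and 13), no filter (32 and 30) and a fold change minimum (79 and 74), and without any 1 library, from 31 and 4 without control replicate 2 to 8162 and 3463 without control replicate 1. The same held for each alternative added after seeing the data that called genes, such as thinned (154 and 114) and background-subtracted counts (373 and 204), except DESeq2 on all samples (624 and 3906). More were lower with DESeq2 (492 higher and 2208 lower), voom (2435 and 2654), voom with sample weights (6849 and 7120), all 15 samples in 1 fit (17 and 25) and the replicate number as a block (1891 and 4111). The median log2 fold change of all genes was -0.14 with TMM, -0.05 with RLE scaling and 0.02 with library totals. The authors' deposited table lists 1871 genes under 0.05 for Mettl3 KO, 549 higher and 1322 lower, including 20 interferon-gamma response genes higher.

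The count was 11625 without control replicate 1, 35 to 65 without any 1 of the other 9 libraries, and 0 with the T cell score as a covariate. It was 42 with all 15 samples in 1 fit, 100 with RLE scaling, 83 with the background covariate and 577 with background-subtracted counts (both added after seeing the data). It was 2700 with DESeq2, which made more false calls in a simulation without structure shared across a library.

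The remaining lists did not pass camera in Mettl3 KO tumors, and none of their members passed over all genes. The medians were 0.47 for regulatory T cell markers, 0.000338 for fibroblast and matrix genes, -0.32 for endothelial markers, 0.39 for skeletal muscle genes and 0.94 for adipocyte genes, with camera adjusted p of 0.482, 0.613, 0.419, 0.736 and 0.0538. Hypoxia and glycolysis genes had a median of -0.26, Wnt targets 0.82, and immediate early and heat shock genes -0.13 (adjusted p = 0.164, 0.275 and 0.701). Against genes of like abundance, the medians of these 8 lists were, in that order, 0.15, 0.49, 0.07, 0.64, 0.39, 0.14, 0.30 and 0.16. Adjusted over the list alone, 1 hypoxia gene fell, and 1 immediate early gene rose and 2 fell. The medians of macrophage, fibroblast and immediate early genes lie closer to 0 than the shift between scalings, and the fibroblast median lay above 0 while camera's direction was down.

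In Mettl14 KO tumors the same interferon-gamma response genes lay above control, with a wider spread between tumors, and no single gene passed over all genes tested. Of the 22 genes 0 passed and 21 rose when adjusted over the list alone, with a median log2 fold change of 1.93. Irf1 stood at 230.5 ± 129.4 against 71.3 ± 27.9 CPM (1.64, SE 0.39, edgeR adjusted p = 0.186). Among the others, Gbp6 had 2.43 (SE 0.42), Iigp1, a GTPase of immune defence, 2.31 (SE 0.40), Gbp7 1.84 (SE 0.34) and Gbp4 2.53 (SE 0.47), each with an adjusted p of 0.130. Reads of the Gbp genes can be shared between near-identical copies. Skeletal muscle genes lay lower, with Myh1, a fast myosin, at 2.05 ± 1.48 against 22.65 ± 8.995 CPM.

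The interferon-gamma list passed camera (adjusted p = 2.189e-21) but had an adjusted p = 0.302 with an estimated correlation. Its score was 6.71 ± 0.88 against 5.09 ± 0.41, with 4 of 5 knockout libraries above every control (exact permutation p = 0.0159, adjusted p = 0.123). Of 25 type I interferon genes 0 passed over all genes and 22 rose when adjusted over the list alone (median 0.90), with 1.98 for Zbp1 (SE 0.37) and 1.44 for Oasl2 (SE 0.29). Of 17 MHC class I genes 12 rose when adjusted over the list alone (median 0.86), with 1.28 for Tapbp (SE 0.33) and 1.08 for Tap2 (SE 0.29), and of 8 MHC class II genes 7 (median 2.69), with 2.70 for Ciita (SE 0.62) and 2.67 for H2-DMb1 (SE 0.75). Of 16 chemokines and cytokines 11 rose when adjusted over the list alone (median 1.497), with 1.87 for Cxcl10 (SE 0.37, 69.1 CPM in replicate 4) and 1.51 for Cxcl11 (SE 0.32). Cxcl9 had 2.32 (SE 0.50, adjusted p = 0.157), Ccl5 2.87 (SE 0.69, adjusted p = 0.189) and Ifng 1.44 (SE 0.75, adjusted p = 0.503). These lists passed camera (adjusted p = 3.079e-15, 2.569e-09, 4.015e-06 and 1.781e-09), and each had an adjusted p = 0.302 with an estimated correlation. By the exact permutation tests of single levels, two-sided and adjusted over 16, Cxcl9 and Cxcl10 had an adjusted p of 0.0181, Ccl5 0.0282 and Irf1 0.0381 in Mettl14 KO tumors. In Mettl3 KO tumors Irf1, Cxcl9, Cxcl10 and Ccl5 had 0.0181.

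Of 15 T cell markers 11 rose when adjusted over the list alone (median 1.54), with 1.54 for Lck (SE 0.41). Of 16 cytotoxic lymphocyte genes 4 did (median 1.12), with 1.87 for Klrk1 (SE 0.47) and 2.29 for Nkg7 (SE 0.62), and of 11 checkpoint and exhaustion genes 4 (median 0.96), with 1.89 for Btla (SE 0.45) and 2.42 for Pdcd1lg2 (SE 0.73). Of 12 neutrophil markers 1 did (median 1.33), with 2.83 for Acod1 (SE 0.55) and 1.72 for the chemokine Cxcl2 (SE 0.58). None of these genes passed over all genes. Camera gave the 4 lists adjusted p of 2.622e-09, 8.47e-07, 7.579e-06 and 9.257e-05. With an estimated correlation, adjusted p = 0.302 for the first 3 and 0.346 for neutrophil markers. Replicate 4 stood apart from the other 4 in Btla, Acod1 and Cxcl2, at 9.54, 97.0 and 22.1 CPM.

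Of 15 skeletal muscle genes 0 passed over all genes and 14 fell when adjusted over the list alone (median log2 fold change -2.71). Myh1 had -3.54 (SE 0.50), Neb, a giant protein of the thin filament, -1.97 (SE 0.29), Myh2 -3.30 (SE 0.51) and Ttn, which encodes titin, -3.17 (SE 0.54), each with an adjusted p of 0.130. The list passed camera (adjusted p = 2.176e-17) and had an adjusted p = 0.302 with an estimated correlation. Its score was 2.40 ± 0.41 in Mettl14 KO and 4.32 ± 0.76 in control tumors, lower in 5 of 5 libraries than in every control (exact permutation p = 0.00794, adjusted p = 0.0820). Of 6 erythroid genes 5 fell when adjusted over the list alone (median -1.85), with -2.14 for Hbb-bs (SE 0.43) and -1.97 for Hba-a1 (SE 0.40). Hypoxia and glycolysis genes had a median of 0.43, and 5 of 15 rose when adjusted over the list alone, with 0.76 for hexokinase Hk2 (SE 0.13) and 0.56 for Ndrg1 (SE 0.16). Ribosomal protein genes had a median of -0.48, and 0 of 20 passed over all genes or adjusted over the list alone, with -0.68 for Rpl5 (SE 0.20) and -0.59 for Rps3 (SE 0.21). Camera gave these 3 lists adjusted p of 7.845e-06, 2.788e-07 and 2.891e-07. With an estimated correlation, adjusted p = 0.302, 0.302 and 0.332.

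**Figure D4:**
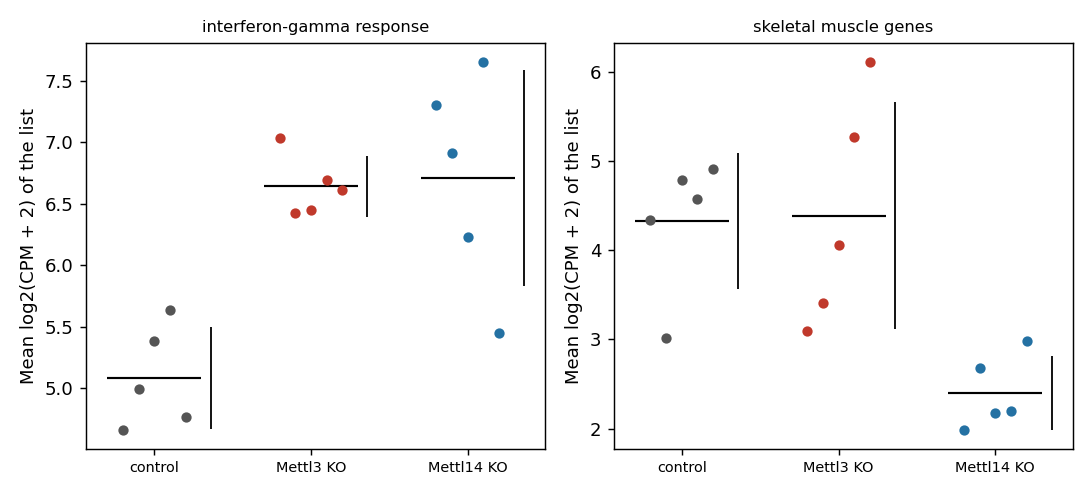
Mean log2(CPM + 2) of the interferon-gamma response list (left) and the skeletal muscle list (right) in each of the 15 libraries, with points for libraries, horizontal lines for group means and vertical lines for SD. The interferon-gamma means are 5.09 in control, 6.64 in Mettl3 KO and 6.71 in Mettl14 KO tumors, and the muscle means are 4.32, 4.39 and 2.40.

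Over all genes, edgeR called 0 of 21555 in Mettl14 KO tumors. At an unadjusted p under 0.05 there were 2444, of which 1022 were higher and 1422 lower, and the smallest adjusted p was 0.130. By unadjusted p, Hk2, Gbp6 and Iigp1 led the higher genes and Myh1, Neb and Myh2 the lower, and none passed. In all, camera passed 21 of the 31 lists, 15 higher and 6 lower, and 0 with an estimated correlation. DESeq2 called 505 genes, 324 higher and 181 lower, voom 0 and voom with sample weights 6. The authors' deposited table lists 503 genes under 0.05, 343 higher and 160 lower, including 19 interferon-gamma response genes higher and 13 muscle genes lower.

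The edgeR count was 1054 without control replicate 1, 148 without Mettl14 KO replicate 5, 6 without control replicate 2 and 0 without any 1 of the other 7 libraries. It was 50 with all 15 samples in 1 fit, 47 without the count filter and, as added after seeing the data, 189 with all samples and the background covariate.

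Among the other lists in Mettl14 KO tumors, camera passed dendritic cell (median 0.99), B cell and plasma cell (1.49), regulatory T cell (0.66) and macrophage markers (0.33) and immediate early and heat shock genes (0.30) as higher. It passed m6A writers, erasers and readers (-0.18), nuclear oxidative phosphorylation genes (-0.19) and mitochondrially encoded genes (-0.63) as lower. None of their members passed over all genes, and adjusted over the list alone 3 dendritic cell, 3 B cell, 1 regulatory T cell and 1 immediate early gene rose. With an estimated correlation these 8 lists had, in that order, adjusted p = 0.302, 0.332, 0.302, 0.623, 0.416, 0.601, 0.620 and 0.614. Camera did not pass fibroblast and matrix (0.53), endothelial (-0.06), keratinocyte (0.02), adipocyte (0.13), epithelial (0.03), cell cycle (-0.13), TGF-beta and mesenchymal (0.01), p53 target (-0.03), unfolded protein response (-0.11) or Wnt target genes (0.04), given with their median log2 fold changes. Adjusted over the list alone, 1 of 11 epithelial genes fell. For epithelial and for TGF-beta and mesenchymal genes camera's direction was down while the median was above 0, and the keratinocyte mean was -0.01. The median of all genes moved from -0.09 with TMM to 0.07 with library totals, which exceeds the size of most of these medians.

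The series sought genes altered in both knockouts. The interferon-gamma response, MHC class II, chemokine and T cell lists had medians above 0 in both, and the erythroid list had medians of -2.01 and -1.85. No gene was called in both by edgeR, since none was called in Mettl14 KO tumors, among the 20173 tested in both. With DESeq2, 236 genes were higher in both and 103 lower in both, where independent lists would share 7.90 and 19.8, and unchanged groups simulated against the same controls shared at most 1. The simulated genes varied independently, without structure shared across a library. Among random labelings of the real libraries, edgeR gave 7623 shared genes in the highest and 0 in the others. The simulation therefore does not exclude such structure as a source of the overlap. In the authors' deposited tables, a total of 258 genes were higher in both and 81 lower in both, with 11.0 and 13.2 for independent lists and 0 in opposite directions. Of the 258, 19 were interferon-gamma response, 9 type I interferon, 8 chemokine and cytokine and 6 T cell genes.

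The log2 fold changes of both knockouts correlated across genes, which are not independent replicates, with r = 0.528 against 0.499 in simulated unchanged groups that share the controls. Their covariance was 0.177 against 0.0764 simulated, a difference of 0.101, and 71.4% of genes had the same sign against 66.5%. These simulated groups also lacked structure shared across a library. With the controls split between the comparisons, r depended on the placement of control replicate 1. It ran from 0.457 to 0.802 in the splits that set this library against Mettl3 KO and from -0.555 to 0.0843 in the others (20 splits in all), and the edgeR overlap had a median of 0. The edgeR overlap was 965 without control replicate 1, 76 without Mettl14 KO replicate 5 and 0 without any 1 of the other 13 libraries.

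Between the knockouts themselves, camera gave its smallest adjusted p to the skeletal muscle and hypoxia lists, although no single gene passed over all genes. Myh1 stood at 31.6 ± 37.4 CPM in Mettl3 KO and 2.05 ± 1.48 CPM in Mettl14 KO tumors (log2 difference 3.99, SE 0.73, edgeR adjusted p = 0.212). Tnnt3, a troponin, had 3.41 (SE 0.66) and the myosin light chain Myl1 3.56 (SE 0.70), and 15 of 15 muscle genes were higher when adjusted over the list alone. Of 15 hypoxia and glycolysis genes 12 were lower in Mettl3 KO when adjusted over the list alone (median -0.68). Ero1l, an oxidase of protein folding, stood at 109.1 ± 15.7 against 203.5 ± 22.5 CPM (-0.90, SE 0.16), Vegfa, the vessel growth factor, at 83.8 ± 9.88 against 139.0 ± 9.38 CPM (-0.73, SE 0.16), and Ndrg1 had -0.91 (SE 0.20).

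Of 12 unfolded protein response genes 8 were lower in Mettl3 KO when adjusted over the list alone (median -0.53), with -0.70 for Dnajb9 (SE 0.23) and -0.62 for Hyou1 (SE 0.21). Of 12 p53 targets 4 were (median -0.55), with -0.60 for Mdm2 (SE 0.16) and -0.95 for the cell cycle inhibitor Cdkn1a (SE 0.25). Camera passed the muscle, hypoxia, unfolded protein response and p53 lists (adjusted p = 2.009e-11, 1.453e-10, 1.053e-05 and 0.000413), and each had an adjusted p = 0.433 with an estimated correlation. The exact permutation test of their scores gave p = 0.00794 and an adjusted p of 0.0615 for all 4. The interferon-gamma list had a median of -0.27 (camera adjusted p = 0.554). In all, camera passed 15 of the 31 lists, 3 higher and 12 lower, and 0 with an estimated correlation or by the exact test.

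Over all genes, edgeR called 0 of 24566 between the knockouts, with 3152 at an unadjusted p under 0.05 and a smallest adjusted p of 0.212. DESeq2 called 68 and voom 0. The edgeR count was 1 without Mettl3 KO replicate 2 and 0 without any 1 of the other 14 libraries.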

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

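The tests of loss of Mettl3 for the abundance trend, of reads spread over the genome for the interferon-gamma and muscle genes, and of loss of the complex for muscle were chosen only after the result was seen.

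Among 294 groups of 5 values screened, 31 had 1 library far from the other 4, where independent normal values would give about 14.7. The CPM were not on a log scale and the groups share libraries, so these counts do not show an excess over chance. Control replicate 1 accounted for 10 of the 31. Its reads outside genes (78.6% against 44.3% to 53.8%), receptor gene level (5343 against 198.7 to 702.1 CPM) and share of satellite-like gene models (21.5% against 0.0535% to 1.25%) lay above the other controls. The satellite-like share ran from 8.51% to 47.1% in Mettl3 KO and from 0.665% to 7.34% in Mettl14 KO libraries. Its list scores were 6.04 for macrophage markers (6.74 to 6.82 in the others), 3.25 for keratinocyte genes (1.88 to 2.18), 5.95 for cell cycle genes (6.67 to 6.88), 5.63 for oxidative phosphorylation genes (6.50 to 6.79) and 8.38 for ribosomal protein genes (9.48 to 9.79). It held Snora57 at 4.87 CPM (17.1 to 21.6) and Xcr1 at 5.52 CPM (0.604 to 1.32).

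Mettl3 KO replicate 1 stood above its group in the B cell and plasma cell score (4.50 against 2.17 to 2.84) and in Igkc (401.7 CPM), Ighm (198.8), Ccl5 (52.2), Cxcl9 (451.3), Calhm6 (21.1) and Fcgr1 (66.6). Mettl14 KO replicate 4 stood above its group in the macrophage score (7.93 against 6.44 to 6.85) and in Cxcl10 (69.1 CPM), Btla (9.54), Acod1 (97.0) and Cxcl2 (22.1). Mettl3 KO replicate 2 stood above its group in Mettl3 (16.3 CPM), Hba-a1 (10.4) and Zmat3 (46.3), and Mettl3 KO replicate 5 in Dnajb9 (21.9). Mettl14 KO replicate 2 had an adipocyte score of 2.81 (2.33 to 2.41 in the others) and a ribosomal protein score of 8.63 (8.99 to 9.13). Control replicate 2 stood above the other controls in Mettl14 (89.8 CPM) and mt-Nd1 (4580 CPM), and Mettl14 KO replicate 5 above its group in Ttn (196.2 CPM).

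Between the knockouts 15 lists differed by camera with the preset correlation, and 0 with an estimated one. Their median log2 differences, Mettl3 KO minus Mettl14 KO, were 3.40 for skeletal muscle, 0.96 for adipocyte and 0.69 for keratinocyte genes. They were -0.68 for hypoxia and glycolysis, -0.55 for p53 target, -0.53 for unfolded protein response, -0.50 for fibroblast and matrix, -0.44 for ribosomal protein and -0.43 for macrophage genes. They were -0.39 for immediate early and heat shock, -0.33 for TGF-beta and mesenchymal, -0.33 for oxidative phosphorylation, -0.32 for m6A, -0.31 for type I interferon and -0.26 for cell cycle genes.

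In Mettl3 KO tumors genes of low level lay above 0 and abundant genes below. Thinning all libraries to the smallest total left 84.7% of the gap between them, which argues against the total of gene counts as its whole cause. Satellite-like models took 8.51% to 47.1% of these counts in Mettl3 KO libraries. Depth on the other genes was therefore not made equal, and its part stays open. Subtracting the receptor gene background left 52.99%, so reads spread over the genome may account for part of it, and this stays open. Control replicate 1 against the other controls showed 177% of the gap with no Mettl3 guide. The main gap, from mean log2 CPM, was 1.58. From edgeR log2 fold changes, the Mettl3 KO gap without that library was 2.36. The Mettl14 KO gap, from edgeR over its own genes, was 0.116. As the measures differ, these gaps compare only roughly with the main one. Since a control library can show the trend, an effect of loss of Mettl3 on this trend cannot be told apart from a difference between libraries.

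Interferon-gamma response genes lay higher in both knockouts. After background subtraction the list score difference was 101.7% of that before in Mettl3 KO (exact permutation p = 0.00794) and 103.6% in Mettl14 KO tumors (exact permutation p = 0.0159). Subtraction removed 3.02% to 10.3% of gene counts in Mettl3 KO and 1.24% to 4.30% in Mettl14 KO libraries, without new scaling. So little could hardly have lowered the difference. The test shows only that the measured background was small beside it. Leaving out any 1 library kept at least 93.1% and 85.5% of the difference, which argues against 1 library as the cause. With the T cell score as a covariate the median log2 fold change was 72.3% of that without in Mettl3 KO tumors, where more T cells stays open (the T cell list shares 0 genes with the interferon-gamma list). It was 48.5% in Mettl14 KO tumors, so more T cells may be behind part of the difference there, and the knockout and T cell number cannot be separated by this design.

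Skeletal muscle genes lay lower in Mettl14 KO tumors, the most abundant being Ttn (81.4 against 717.6 CPM), Myh4 (5.39 against 91.5) and Neb (23.7 against 89.6). Background subtraction left 108.8% of the score difference (exact permutation p = 0.00794). Receptor genes took 1162 ± 551 CPM in Mettl14 KO and 1430 ± 2200 CPM in control libraries (exact permutation p = 0.984). The control mean was raised by control replicate 1, at 5343 CPM. The other controls lay between 198.7 and 702.1 CPM, and the Mettl14 KO libraries between 573.8 and 1954 CPM. With so little background in most controls, subtraction could hardly have lowered the difference. It therefore does not decide on reads spread over the genome. Mettl3 KO exceeded Mettl14 KO tumors by 1.98 in score (exact permutation p = 0.00794). The Mettl3 KO scores ran from 3.10 to 6.11 and the control scores from 3.02 to 4.90. The deviations of the 15 genes from their group means correlated across the 15 libraries with a mean pairwise r of 0.851, so muscle tissue taken with some tumors may be a source. Such tissue could hide a fall in Mettl3 KO tumors. The comparison of the knockouts, chosen after the scores were seen, therefore does not decide on loss of the shared complex. An effect of Mettl14 apart from the complex was not tested.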

How the results depend on the processing

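The covariate and subtraction of background, the 15-sample fits other than the plain one, fits without the libraries richest in reads outside genes, thinning and the exact tests were chosen after seeing the data, as were the plain 15-sample fit for genes shared by both knockouts and library totals for the gene count between the knockouts; the others were planned. Of the counts of genes, 56 alternatives stayed within 1.5 times and 49 did not; of the counts of lists, 48 and 13. Single list results were the same in 850 cases, weaker in 259 and reversed in 13. Named gene results were the same in 2166, stronger in 374, weaker in 342 and reversed in 6. Of the 106 named gene results, only 38 passed in the main fit, all in Mettl3 KO tumors. A gene that passed in neither fit counts as the same, and only those 38 could become weaker. The count of same results is therefore no measure of how well the passing genes held. Unless said otherwise, the cause was not tested.

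The 266 genes of Mettl3 KO tumors became 100 with RLE scaling, 122 with library totals, 62 without a filter, 81 with a mean of at least 1 CPM and 153 with an absolute log2 fold change of at least 1 as well. They became 2700 with DESeq2, 5089 with voom, 13969 with sample weights, 42 with all 15 samples in 1 fit and 0 with the T cell covariate. They became 83 with the background covariate, 577 with subtraction, 0 with all samples and the background covariate, 15333 with all samples but control replicate 1, 4530 with DESeq2 on all samples, 8858 with voom on all samples and 8124 without both libraries richest in reads outside genes. Leaving out 1 library gave 35 (control replicate 2) to 11625 (control replicate 1).

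The 0 genes of Mettl14 KO tumors (edgeR; 2444 at an unadjusted p under 0.05) became 47 without a filter, 505 with DESeq2, 0 with voom, 6 with sample weights and 50 with all samples. They became 189 with all samples and the background covariate, 597 with all samples but control replicate 1, 404 and 12 with DESeq2 and voom on all samples, and 1054 without the richest libraries, of which only control replicate 1 is in this comparison. Leaving out 1 library gave 0 to 1054 (control replicate 1). The 0 genes between the knockouts became 68 with DESeq2, and 0 to 1 with 1 library left out. The 0 genes shared by both knockouts became 339 with DESeq2, 16 without a filter, 18 with all samples (chosen after seeing the data), and 0 to 965 with 1 library left out.

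The replicate numbers gave no steady sign of pairing. Correlations of same-numbered deviations ran from -0.24 to 0.62 (Mettl3 KO and control), -0.75 to 0.22 (Mettl14 KO and control) and -0.67 to -0.11 (the knockouts). Replicates 1 and 5 of Mettl3 KO and control had 0.62 and 0.57, so pairing was not excluded. With the number as a block the gene counts were 6002, 14 and 12 for Mettl3 KO, Mettl14 KO and both; the block moved no list count by over 1.5 times.

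With an estimated correlation, camera called 0 lists in each comparison. The exact test of scores called 10 in Mettl3 KO, 0 in Mettl14 KO and 0 between them, with and without subtraction. Fry called 0 in Mettl14 KO and 1 between the knockouts. With subtraction camera called 6 between them, of which 5 were among the lists called without it. Leaving out 1 library gave 13 to 23.

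Camera's direction reversed with the T cell covariate for B cell (adjusted p = 0.276), cell cycle (4.963e-12) and oxidative phosphorylation genes (0.699) in Mettl3 KO, and for macrophage (0.234), neutrophil (0.657) and mitochondrially encoded genes (0.653) in Mettl14 KO tumors. It reversed for Mettl3 KO cell cycle genes with the background covariate (0.538) and subtraction (0.940). Between the knockouts it reversed with the background covariate for type I interferon (0.858), keratinocyte (0.890), cell cycle (0.0301) and oxidative phosphorylation genes (0.581), and with subtraction for cell cycle genes (0.0503). With the T cell covariate the log2 fold changes were -0.21 for Ccl5, -0.93 for Igkc, -0.073 for Ighm and -0.10 for Csf3r in Mettl3 KO, and 0.012 for Mettl14 and -0.23 for Ifng in Mettl14 KO tumors.

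The smallest libraries, 4.35 to 5.52 M gene counts, limit what can be seen of genes of low level.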

Other observations

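Cd163, the hemoglobin scavenger receptor of macrophages, stood at 14.3 ± 3.07 CPM in Mettl3 KO and 36.5 ± 12.4 CPM in Mettl14 KO tumors, lower in 5 of 5 libraries than in every Mettl14 KO library (log2 difference -1.35, SE 0.24, edgeR adjusted p = 0.212). It was chosen here after its values were seen. Adjusted over the list alone, 2 of 16 macrophage markers and 3 of 14 fibroblast and matrix genes were lower in Mettl3 KO than in Mettl14 KO tumors, and 2 of 10 adipocyte genes were higher.

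Other splits of the same libraries into groups of 5 were drawn, 100 for each comparison with the real one included. For the genes changed in Mettl3 KO tumors 5 of 100 splits gave as many (266 in the real one, 13468 in the highest other), so chance was not excluded. The other 4 each put control replicate 1 with Mettl3 KO replicates 1, 3 and 4, and their far larger counts point to a structure of the samples. These libraries had the largest shares of reads outside genes among the 15 (78.6%, 71.6%, 69.2% and 78.0%). Apart from the real split, no drawn split that parted them called a gene. Keeping them together was not enough, since splits that added control replicate 3 or 5 to them gave 0 genes. Whether reads outside genes drove the counts of these splits was not tested. For Mettl14 KO, both knockouts and the difference between the knockouts, where the real count was 0, every split gives as many by definition, so this test says nothing about chance. The highest other splits had 5414, 7623 and 8 genes, and the first pair of counts point to a structure of the samples. For lists, 8 of 100 gave as many as the 20 of Mettl3 KO (highest other 22), 15 as many as the 21 of Mettl14 KO (25) and 65 as many as the 15 between the knockouts (25), so chance was excluded for none of these list counts.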
